A study of Homo sapiens with 36 samples.

How the data were processed

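The series profiled HMC3 cells, an established human microglial cell line, after exposure to perfluorooctane sulfonate (PFOS), a persistent perfluorinated surfactant. Per the labels, cells received vehicle, 25 µM PFOS or 50 µM PFOS for 24 h, and for the recovery groups the medium was then replaced with PFOS-free medium for a further 24 h. The series holds 36 samples, of which 18 are RNA-seq libraries and 18 are H3K27ac CUT&Tag libraries. The CUT&Tag libraries were not analysed here. The RNA-seq libraries form 6 groups of 3, which the labels call biological replicates; whether these were separate cultures set up on separate days is not given in the sources used here, so p-values measure the spread between these libraries.

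Per the labels' protocols, total RNA was extracted with TRIzol, and libraries were made by a Smart-seq2 workflow with poly(A) selection and sequenced as paired ends. Smart-seq2 amplifies full-length cDNA by PCR without molecular identifiers and without marking strand, so counts are not independent molecules, and intervals and floors given here cover counting error only. The authors deposited 1 table of raw counts per gene symbol, with 1 column per library and no normalization, per the file headers. Trimmomatic, STAR, DESeq2 and MACS2 are named for the series, with the builds GRCh38 and hg38, per the submitters' processing notes. Their versions, the counting tool, the gene annotation and the strand setting are not given in the sources used here. Reads of overlapping or antisense genes therefore cannot be told apart, and genes with near-identical copies, such as ribosomal protein genes and their processed pseudogenes, metallothioneins, actins and histones, are uncertain in how reads were divided among copies. Each column name matched the labels of 1 library, and 0 columns were left without a sample.

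The table lists 25344 gene symbols, of which 7391 had no count in any library. Of all symbols, 95.3% were found among the symbols or synonyms of NCBI RefSeq genes on GRCh38.p14, which supplied gene positions and gene spans. Some symbols in the table are older names, and these are kept here (HIST1H1C is now H1-2, and HIST1H4H is now H4C8). Total counts per library ranged from 582233 to 4346627, which is shallow for bulk RNA-seq. Replicates were compared before averaging with a chi-square test over genes with at least 10 counts in the pair. The chi-square per degree of freedom ranged from 1.29 to 21.4, where 1 is counting noise of independent molecules. Duplication by PCR also raises this value, so it does not tell differences between replicates from duplication, and each library was counted separately.

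Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10 and the 6 groups, which left 9847 genes holding 99.2% of the counts, and libraries were scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted to all 18 libraries, so that the groups share 1 estimate of the spread. Where 1 group varies more than the others, this spread can be too small for it and too large for the rest. The median biological coefficient of variation was 16%. Comparisons were the 4 contrasts of PFOS with vehicle, 50 with 25 µM PFOS at each time, the difference between the recovery and 24 h effects at each dose, and vehicle after recovery with vehicle at 24 h. P-values are two-sided and adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and "called" means past this threshold. Log2 fold changes are given with their standard error (SE). Values in CPM (counts relative to library size) use the TMM-scaled library sizes and are means ± SD of 3 libraries. Where all libraries of a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group, set over the group and not per library. Shares of counts within a single library carry 95% Wilson intervals, which treat counts as independent and are thus too narrow.

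A total of 31 gene lists was fixed before the data were examined, covering stress responses, lipid metabolism, inflammation, growth, matrix, organelles, chromatin and markers of cell types. The 23 lists with at least 5 tested members were tested with camera in limma 3.58.1 at its preset inter-gene correlation of 0.01, adjusted over the lists. Camera asks whether a list's genes moved relative to all other genes. Each list was tested again with its correlation estimated from the data, and with fry, which asks whether the list's genes moved on balance in 1 direction. Members passing the test are also counted with p-values adjusted over the list alone.

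Named genes follow a rule that was also fixed in advance. It took, for each contrast of PFOS with vehicle, the 6 largest increases and the 6 largest decreases among called genes with a mean of at least 5 CPM in either group and no overlap between the 3 and 3 libraries, leaving out clone-based and non-coding locus names. For the vehicle contrast it took 4 and 4. From each list it took the 2 members with the smallest adjusted p at 24 h of 50 µM PFOS and the 1 with the smallest after recovery, or the most abundant member where none was called. Of the genes the rule gave, 99 are reported and the others are not reported here, without replacement, while all genes stay in the tests, counts and lists. In addition, ASNS, SERPINE2 and RPLP0 were named after their values were seen.

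The pipeline was tested on simulated counts for the 9847 genes with 66 or 67 genes changed at each fold size and the integrated stress response list raised 2-fold. For 25 µM PFOS at 24 h it called 97% of 4-fold changes, 47.8% of 2-fold changes and 5.97% of 1.5-fold changes. For 50 µM at 24 h these shares were 92.4%, 40.3% and 5.97%, for 25 µM after recovery 92.4%, 46.3% and 7.46%, and for 50 µM after recovery 92.4%, 49.3% and 5.97%. Unchanged genes made up 7.81%, 2.65%, 3.36% and 4.96% of the simulated calls in the same order. The simulated libraries differed by independent noise at the spread shared by all groups. They do not imitate libraries 2 and 3 of the 50 µM recovery group, which stand apart from the others. The shares given for that group may therefore not hold for the real libraries. Changes of 1.5-fold are thus mostly missed at this depth and number of libraries.

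Alternatives planned at the same stage as the lists were RLE scaling, no filter on low counts, a filter at 1 CPM in at least 6 libraries (planned as a stricter one, although at this depth it kept 12913 genes, more than filterByExpr), DESeq2 1.42.0, only the libraries of the contrast, the replicate number as a block, counts thinned to the smallest library, leaving out each library in turn, and the list tests above. A refit without libraries 2 and 3 of the 50 µM recovery group and a refit with each library's trend against gene span removed were added after the data were seen. The first of these leaves 1 library in that group, tested against a spread taken from the other groups, so its calls assume that the lone library varies like them. Figures were drawn with matplotlib.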

Results

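Gene expression was measured by RNA-seq in HMC3 cells, a human microglial line, to follow how transcript levels responded to PFOS and how far they returned after its removal. There were 6 groups of 3 libraries: vehicle, 25 µM PFOS and 50 µM PFOS, each sampled directly after 24 h of exposure or after a further 24 h of recovery in PFOS-free medium. Total counts per library were 882883, 2753911 and 3435906 for vehicle at 24 h, 1367642, 3679746 and 1560006 for 25 µM PFOS and 967960, 973434 and 1931726 for 50 µM PFOS. After recovery they were 1319266, 3982818 and 2151038 for vehicle, 582233, 4346627 and 905359 for 25 µM PFOS and 841252, 1228047 and 755905 for 50 µM PFOS.

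Cells exposed to 50 µM PFOS for 24 h lay apart from the other groups on the second principal component of log2 CPM (17.3% of the variance), with scores of -42.7, -44.8 and -37.3 against 16.5, 18.1 and 15.1 for vehicle at 24 h. The 25 µM libraries lay between them, at -2.9, -2.7 and -3.4. The first component (40.5%) set apart the 50 µM recovery libraries, whose scores were 14.9, 105.3 and 52.9, while the other 15 libraries lay between -29.4 and 3.4. In the same 3 libraries the 86 ribosomal protein genes took 2.94%, 7.58% and 5.03% of the counts, with 95% Wilson intervals of 2.91% to 2.98%, 7.53% to 7.62% and 4.98% to 5.08%, against 1.21% to 2.43% elsewhere. Replicates of this group also correlated least, with Pearson correlations across genes of 0.849, 0.937 and 0.915, where all other replicate pairs reached at least 0.951. By chi-square per degree of freedom its pairs (21.4, 4.46 and 9.09) overlapped with those of vehicle after recovery (5.55, 4.51 and 10.6).

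**Figure D1:**
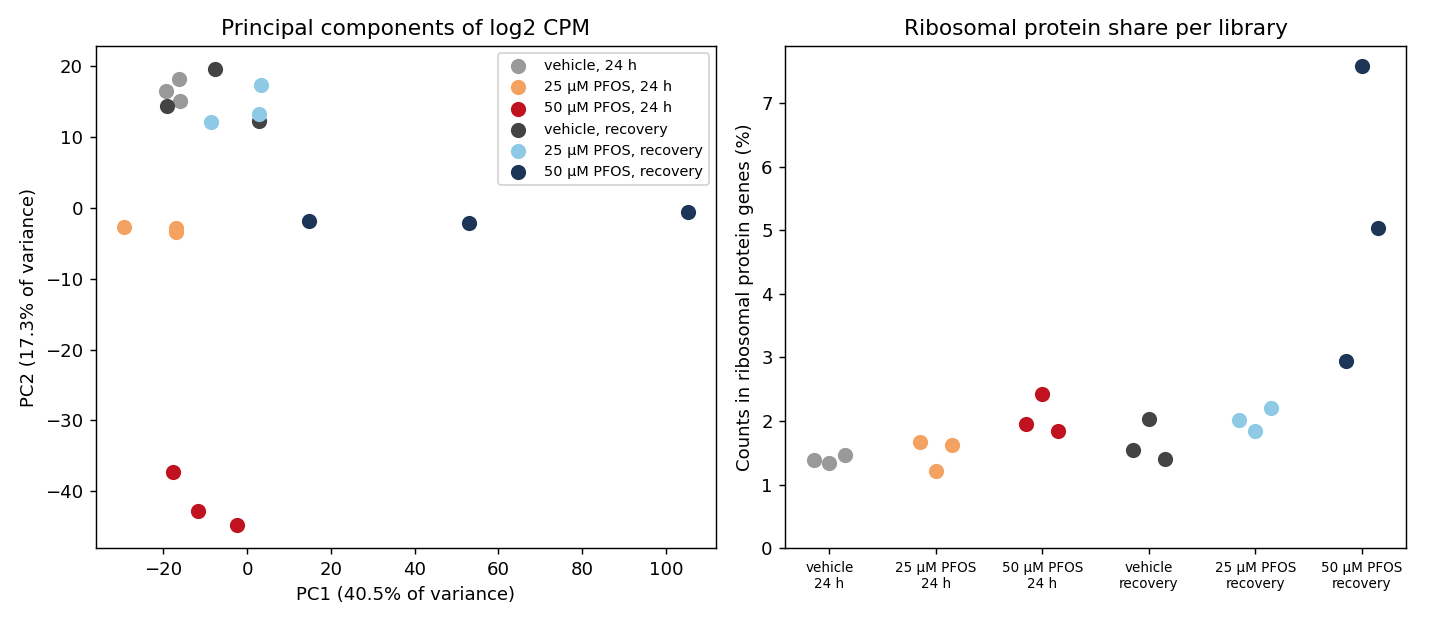
Left, scores of the 18 libraries on the first and second principal components of log2 CPM, coloured by group; right, the percentage of each library's counts in ribosomal protein genes, with 1 point per library. The 50 µM recovery libraries reach 105.3 on the first component and 7.58% ribosomal protein counts, and the 50 µM libraries at 24 h lie lowest on the second component.

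Exposure to 25 µM PFOS for 24 h raised genes of the integrated stress response, the ATF4-driven program for amino acid supply and translational stress. Of its 24 tested genes 17 rose and 0 fell (23 and 0 adjusted over the list alone), with a median log2 change of 1.01 (camera adjusted p = 2.94e-85). TRIB3, a pseudokinase induced by ATF4 (chromosome 20: 380760-397559, GRCh38), rose from 54.7 ± 8.89 to 340 ± 59.6 CPM (SD, n = 3), a log2 change of 2.60 ± 0.25 (SE; edgeR adjusted p = 4.28e-06). STC2, a secreted glycoprotein of stressed cells, rose by 1.15 ± 0.15 on the log2 scale, and CHAC1, which degrades glutathione, by 1.85 ± 0.32. The glycine transporter SLC6A9 rose by 2.17 ± 0.26 and the secreted peptide ADM2 by 2.27 ± 0.34. ASNS, asparagine synthetase, which was chosen after its values were seen, rose by 2.16 ± 0.20.

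Genes of protein folding in the endoplasmic reticulum (ER) rose with them at 25 µM, although fewer passed the test. In the ER chaperone list 2 of 19 genes rose (7 adjusted over the list alone; median 0.32, adjusted p = 5.2e-08). They were HSPA5, the main ER chaperone (chromosome 9: 125234853-125241343), at 0.81 ± 0.11, and HERPUD1, a component of ER-associated degradation, at 0.81 ± 0.14. NRF2 targets, which serve antioxidant defence, had 4 of 17 genes higher (5 over the list alone; median 0.27, adjusted p = 0.000107), among them the cystine transporter SLC7A11 at 2.12 ± 0.33 and thioredoxin reductase TXNRD1 at 0.78 ± 0.15. Lysosome and autophagy genes had 2 of 22 higher both ways (median 0.17, adjusted p = 0.00126). The p53 target list shifted upward with 0 of 18 genes called (2 over the list alone; median 0.27, adjusted p = 0.0015).

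Lipid genes moved in both directions at 25 µM. ANGPTL4, a PPAR-induced inhibitor of lipoprotein lipase (chromosome 19: 8364155-8374370), had no count in vehicle and reached 13 ± 4.86 CPM (n = 3), at least 30.4-fold higher. The PPAR target and fatty acid oxidation list had 3 of 13 genes higher (4 over the list alone), with a median of 0.21 that ANGPTL4 at its bound leaves in place (adjusted p = 3.52e-06). The cholesterol synthesis and uptake list fell, with 1 of 24 genes lower (4 over the list alone; median -0.36, adjusted p = 2.24e-08). Its member CYP51A1, a sterol demethylase (chromosome 7: 92112153-92134803), was at 332 ± 26.8 CPM in vehicle and 269 ± 1.73 at 25 µM, a log2 change of -0.30 ± 0.13 that did not pass (adjusted p = 0.489). The interferon response list fell with 1 of 15 genes lower (5 over the list alone; median -0.52, adjusted p = 6.35e-06), led by the antiviral gene IFIT1 (chromosome 10: 89392623-89406487) at -1.69 ± 0.27. Heat shock proteins (median -0.24, 0 of 15 called both ways, adjusted p = 0.0109) and mitosis genes (median -0.15, 0 of 18 called both ways, adjusted p = 0.0109) shifted downward in camera, with adjusted p = 0.0629 and adjusted p = 0.148 with an estimated correlation.

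Outside these programs, PTX3, a secreted pattern recognition protein (chromosome 3: 157436850-157443633), rose by 1.83 ± 0.26 at 25 µM, and the collagen crosslinking enzyme LOX by 0.95 ± 0.16. SPARC, a matrix glycoprotein (chromosome 5: 151661096-151686915), fell by 0.75 ± 0.12 on the log2 scale. In all, 77 genes rose and 45 fell among 9847 tested, 58 of them at least 2-fold. The 2 groups did not overlap for 22.9% of genes, where chance gives 10%. The count of 122 fell to 75, 60 and 63 without vehicle libraries 1, 2 and 3, to 62, 49 and 58 without 25 µM libraries 1, 2 and 3, and to 62 in thinned counts, and it was 416 with these 6 libraries alone. TXNRD1 lost its call without 25 µM library 2, with adjusted p from 2.55e-05 to 0.0632 over the alternatives.

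At 50 µM for 24 h genes of the stress programs rose against vehicle. Of 24 integrated stress response genes 18 rose and 0 fell (19 and 0 over the list alone; median 1.49, adjusted p = 1.18e-38). TRIB3 reached 849 ± 87.5 CPM, a log2 change of 3.92 ± 0.26 (adjusted p = 1.9e-09), and DDIT3, the pro-apoptotic transcription factor CHOP, rose by 2.49 ± 0.26. Of 19 ER chaperone genes 12 rose (13 over the list alone; median 0.79, adjusted p = 1.53e-14). HSPA5 rose from 1820 ± 86.4 to 6250 ± 165 CPM, by 1.78 ± 0.11, and HERPUD1 by 1.93 ± 0.14. The lysosome and autophagy list had 7 of 22 genes higher and 1 lower (11 and 1 over the list alone; median 0.38, adjusted p = 1.08e-05), with the autophagosome genes WIPI1 at 1.78 ± 0.14 and MAP1LC3B at 1.62 ± 0.17.

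Antioxidant and metal-binding genes rose at 50 µM as well. NRF2 targets had 7 of 17 genes higher and 2 lower (8 and 2 over the list alone; median 0.15, adjusted p = 0.000337). NQO1, a quinone reductase (chromosome 16: 69709401-69726560), rose by 1.35 ± 0.17 and TXNRD1 by 1.5 ± 0.15. Both tested metallothionein and zinc export genes rose, with a median of 3.12, too few for a set test. MT2A, a metal-binding metallothionein (chromosome 16: 56608584-56609497), went from 39.4 ± 8.85 to 265 ± 29.5 CPM, a log2 change of 2.70 ± 0.35, and its near-identical relatives make the split of reads among them uncertain. The p53 target list had 3 of 18 genes higher and 1 lower both ways (median 0.47, adjusted p = 0.0152; adjusted p = 0.0564 with an estimated correlation), with the cell cycle inhibitor CDKN1A at 1.26 ± 0.18. In the heat shock protein list 1 of 15 genes rose both ways (median -0.06, adjusted p = 0.695).

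Genes of sterol and fatty acid synthesis fell at 50 µM. Of 24 cholesterol genes 22 fell and 0 rose (23 and 0 over the list alone; median -1.25, adjusted p = 6.69e-26). CYP51A1 fell to 114 ± 5.23 CPM, a log2 change of -1.54 ± 0.14 (adjusted p = 1.09e-07). Of 14 fatty acid synthesis genes 9 fell and 1 rose both ways (median -0.77, adjusted p = 3.34e-05; adjusted p = 0.0577 with an estimated correlation), with the acetyl-CoA synthetase ACSS2 at -2.10 ± 0.20. ANGPTL4 reached 37.5 ± 5.59 CPM, at least 87.8-fold above vehicle, and the lipid droplet protein PLIN2 rose by 1.33 ± 0.19. In the PPAR list 5 of 13 genes rose and 2 fell both ways, and its median of -0.11 had the opposite sign to its mean of 0.83 and to its upward test (adjusted p = 0.0473; adjusted p = 0.0861 with an estimated correlation). Of 3 tested LXR targets, which export sterols, ABCA1 rose by 2.20 ± 0.26, and the list's median was 0.34.

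Proliferation and matrix genes fell at 50 µM. Of 18 mitosis genes 14 fell and 0 rose (15 and 1 over the list alone; median -0.70, adjusted p = 2.58e-09), among them the kinase AURKA at -0.97 ± 0.12 and the kinesin KIF20A at -1.26 ± 0.15. Of 23 DNA replication genes 7 fell both ways (median -0.38, adjusted p = 0.00382; adjusted p = 0.0564 with an estimated correlation), with RRM2, a ribonucleotide reductase subunit, at -0.73 ± 0.12. Of 16 extracellular matrix genes 7 fell and 1 rose (9 and 1 over the list alone; median -0.78, adjusted p = 0.00187; adjusted p = 0.364 with an estimated correlation). SPARC changed by -1.10 ± 0.12 and the collagen gene COL5A2 by -1.92 ± 0.21, while LOX was the gene that rose, by 2.07 ± 0.16. Of 11 TGF-beta and YAP targets 4 fell and 2 rose (6 and 2 over the list alone; median -0.44, adjusted p = 0.0151; adjusted p = 0.0577 with an estimated correlation), with the growth factor TGFB2 at -2.32 ± 0.20.

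Of 15 interferon response genes 6 fell and 0 rose (7 and 1 over the list alone; median -0.77, adjusted p = 0.00187), with IFIT1 down from 31.2 ± 8.6 to 4.35 ± 1.25 CPM (-2.67 ± 0.34) and the antiviral GTPase MX1 at -2.42 ± 0.40. The NF-kB and cytokine list did not pass (2 of 8 genes higher, 3 over the list alone; median 0.35, adjusted p = 0.219), while its chemokine CXCL8 rose by 2.76 ± 0.47. PTX3 reached 232 ± 28.7 CPM, a log2 change of 4.34 ± 0.25. MMP1, an interstitial collagenase (chromosome 11: 102789919-102798160), rose from 1.78 ± 0.588 to 140 ± 5.76 CPM, by 6.41 ± 0.36 (adjusted p = 1.76e-10). Of 13 immediate early genes 3 rose both ways (median 0.36, adjusted p = 0.043; adjusted p = 0.332 with an estimated correlation), with the AP-1 gene FOSL1 at 1.35 ± 0.15. Ribosomal protein genes shifted upward, with 7 of 32 higher both ways (median 0.50, adjusted p = 0.00019; adjusted p = 0.577 with an estimated correlation), and their share of counts in the 50 µM libraries was 1.85% to 2.43%.

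Other lists showed few calls at 50 µM and did not pass the set test, or had too few tested genes for it. Of 14 hypoxia and glycolysis genes 1 rose and 2 fell (2 and 2 over the list alone; median -0.03, adjusted p = 0.405), with lactate dehydrogenase LDHA at -1.28 ± 0.15. The 28 nuclear-encoded respiratory chain genes had 0 calls both ways (median -0.04, against a mean of 0.02; adjusted p = 0.983), and 0 of the 13 mitochondrially encoded genes were in the table. Of 23 histone acetylation writers, erasers and readers 2 fell (1 over the list alone; median 0.15, adjusted p = 0.772), with the deacetylase HDAC2 at -0.63 ± 0.15. Of 6 replication-dependent histones 1 rose both ways (median 0.40, adjusted p = 0.388), and of 4 xenobiotic receptor targets the efflux pump ABCB1 fell by 1.43 ± 0.19 (list median 0.24, mean -0.08). In all, 904 genes rose and 944 fell, 842 of them at least 2-fold, and the groups did not overlap for 41.4% of genes, where chance gives 10%. The count of 1848 was 1139 without vehicle library 2, 1184 in thinned counts and 2860 with these 6 libraries alone.

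**Figure D2:**
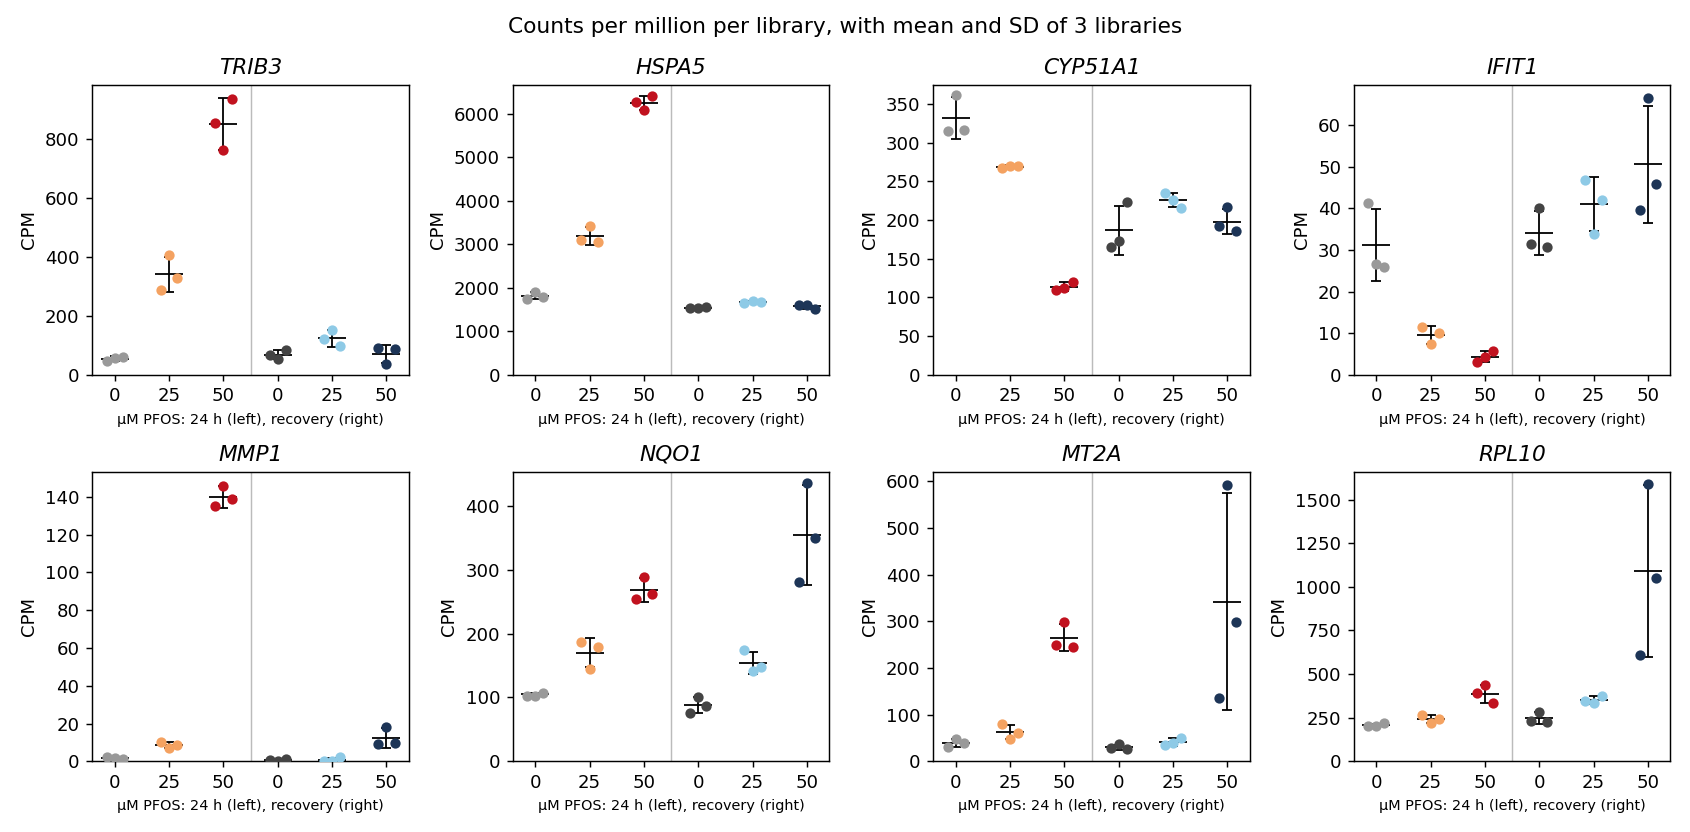
CPM of 8 genes in each library, with 1 point per library and bars for the mean and SD of the 3 libraries of a group. TRIB3, HSPA5, CYP51A1 and IFIT1 moved at 24 h of 50 µM PFOS and were not called against the vehicle of the same time after recovery in these CPM, which carry no correction for gene span, whereas MMP1, NQO1, MT2A and RPL10 were also above vehicle after recovery from 50 µM PFOS.

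The doses differed at 24 h in some of these genes, and lists were not tested between doses. HSPA5, TRIB3, PTX3 and MMP1 were higher at 50 than at 25 µM (adjusted p = 7.57e-06, 0.00113, 3.84e-07 and 1.71e-08), and CYP51A1 was lower (adjusted p = 9.65e-06). For the stress genes CHAC1, ASNS, SLC7A11, SLC6A9 and ADM2 the doses were not shown to differ (adjusted p = 0.0557, 0.0824, 0.0851, 0.0912 and 0.626), nor for IFIT1 (adjusted p = 0.143). In all, 373 genes were higher and 356 lower at 50 than at 25 µM, and the groups did not overlap for 35.2% of genes, where chance gives 10%. The count of 729 was 423, 347 and 439 without 25 µM libraries 1, 2 and 3, 407 and 396 without 50 µM libraries 1 and 2, 386 in thinned counts, and 1932 with these 6 libraries alone. Of the 122 genes called at 25 µM, 117 were called in the same direction at 50 µM (74 higher, 43 lower) and 0 in the opposite one, where independent lists would share 11.4 in the same direction. This count of 117 was 75, 57 and 60 without vehicle libraries 1, 2 and 3, 62, 48 and 57 without 25 µM libraries 1, 2 and 3, 59 in thinned counts and 372 from fits of each contrast's own libraries. Both comparisons share their vehicle libraries, which are too few to divide, so part of the overlap may come from them. In a fit of the 9 libraries at 24 h the covariance of log2 changes was 0.155 against 0.0266 for simulated unchanged groups, a difference of 0.128. In that fit 349 genes were shared, against 0 in 20 simulations. The simulations held no changed gene, so hardly any call was possible in them. This count thus cannot show how much of the overlap comes from the vehicle libraries. The correlation of log2 changes in that fit was 0.68, against 0.451 in the simulations, and 71.2% of genes had the same sign, against 65.2%.

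After 25 µM PFOS and recovery, 0 genes passed edgeR's test, with 693 genes at an unadjusted p under 0.05 and a lowest adjusted p of 0.488, and DESeq2 called 1. The groups did not overlap for 13.8% of genes, where chance gives 10%. TRIB3 lay at 123 ± 27.8 CPM against 67.3 ± 14.7 in vehicle (log2 change 0.90 ± 0.25, adjusted p = 0.523), and NQO1 at 154 ± 17.8 against 87.7 ± 12.3 (0.79 ± 0.17, adjusted p = 0.488). As sets, integrated stress response genes were higher (median 0.46, 11 of 24 over the list alone, adjusted p = 1.43e-15), as were NRF2 targets (median 0.27, 5 of 17 over the list alone, adjusted p = 0.000172), p53 targets (median 0.20, 0 of 18 over the list alone, adjusted p = 0.00224) and interferon response genes (median 0.63, 2 of 15 over the list alone, adjusted p = 3.09e-06). Mitosis genes were lower (median -0.21, 5 of 18 over the list alone, adjusted p = 3.09e-06). Camera at its preset called 9 lists here, while a wrong split of the same libraries called up to 6, so its p-values cannot be read alone. Further lists passed camera's preset but not an estimated correlation. Ribosomal proteins had a median of 0.42 (adjusted p = 2e-09; adjusted p = 0.44 with an estimated correlation), and their share of counts was 1.84% to 2.21% in these libraries against 1.41% to 2.03% in vehicle. Cholesterol genes had a median of 0.17 (adjusted p = 0.0176; adjusted p = 0.0869 with an estimated correlation) and PPAR targets one of 0.09 (adjusted p = 0.0384; adjusted p = 0.0892 with an estimated correlation). Matrix genes had a median of -0.12 (adjusted p = 0.0457; adjusted p = 0.648 with an estimated correlation), with no call for the extracellular matrix list once the gene-span trend was removed. In these 3 libraries log2 CPM relative to vehicle fell with gene span (Spearman rho across genes of -0.16, -0.28 and -0.21), as did the log2 changes of the contrast (rho of -0.26 over 9781 genes). Vehicle libraries after recovery had rho of -0.07, -0.15 and 0.19 by the same measure.

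After 50 µM PFOS and recovery, the integrated stress response, ER chaperone and cholesterol lists were not called. Of 24 integrated stress response genes 2 were higher and 4 lower both ways (median -0.23, adjusted p = 0.166). TRIB3 lay at 70.8 ± 30.6 CPM against 67.3 ± 14.7 in vehicle (0.05 ± 0.27), whereas DDIT3 was still higher by 1.86 ± 0.24. ER chaperones had 5 of 19 genes higher and 2 lower (5 and 3 over the list alone; median 0.09, adjusted p = 0.534), with HSPA5 at 1570 ± 51.1 against 1540 ± 9.03 CPM (0.03 ± 0.11, and -0.34 with the gene-span trend removed). Of 24 cholesterol genes 5 were higher and 3 lower (5 and 4 over the list alone; median 0.09, adjusted p = 0.708), with CYP51A1 at 198 ± 16.3 against 187 ± 31.6 CPM (0.09 ± 0.14). Interferon response genes had 6 of 15 higher and 2 lower (7 and 2 over the list alone; median 0.42, adjusted p = 0.166), with the ubiquitin-like modifier ISG15 at 2.09 ± 0.29, a call lost without 50 µM recovery libraries 2 and 3 (ISG15 then at 1.21), where the range of its adjusted p over the alternatives was 1.82e-15 to 0.0546. Without those libraries edgeR called 0 interferon genes (median 0.21), 0 cholesterol genes (median -0.05), 1 ER chaperone, higher (median 0.02), and 1 integrated stress response gene each way (median -0.26). With the gene-span trend removed, 2 ER chaperones were higher and 6 lower (median -0.03), and 1 integrated stress response gene was higher and 7 lower (median -0.32).

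Other changes were present after recovery from 50 µM. NQO1 was higher by 2.01 ± 0.17 (354 ± 77.4 against 87.7 ± 12.3 CPM, adjusted p = 1.01e-06), and 6 of 17 NRF2 targets were higher both ways (median 0.35, adjusted p = 0.000296). The NRF2 targets TXNRD1 and SLC7A11, which had risen at 24 h, were not called (0.12 ± 0.15 and 0.51 ± 0.35). MT2A lay at 342 ± 232 against 30.3 ± 5.44 CPM (3.48 ± 0.36), and the tested metallothionein genes had a median of 3.40. MMP1 lay at 12.4 ± 5.03 against 0.713 ± 0.688 CPM (4.38 ± 0.59). Matrix genes had 13 of 16 members lower and 0 higher both ways (median -1.15, adjusted p = 3.76e-10; adjusted p = 0.209 with an estimated correlation), with SPARC at -1.18 ± 0.12 and COL5A2 at -1.49 ± 0.21. Fatty acid synthesis genes had 5 of 14 lower and 1 higher (7 and 1 over the list alone; median -0.43, adjusted p = 0.0228; adjusted p = 0.324 with an estimated correlation). TGFB2 was lower by 1.45 ± 0.19, ABCB1 by 1.64 ± 0.21 and the semaphorin SEMA5A, an axon guidance cue, by 3.12 ± 0.54.

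Ribosomal protein and nuclear-encoded respiratory chain genes were higher after recovery from 50 µM, together with the standing apart of these libraries on the first principal component (14.9, 105.3 and 52.9). All 32 ribosomal protein genes of the list were higher (32 over the list alone; median 1.99, adjusted p = 1.57e-33; adjusted p = 0.209 with an estimated correlation). RPL10, a large subunit protein (chromosome X: 154398065-154402339), lay at 1090 ± 491 against 249 ± 31.8 CPM, a log2 change of 2.12 ± 0.23, and RPL3 changed by 1.04 ± 0.14. Of 28 respiratory chain genes 19 were higher (23 and 1 lower over the list alone; median 1.17, adjusted p = 5e-10; adjusted p = 0.262 with an estimated correlation), with the complex I subunit NDUFB8 at 1.91 ± 0.24. Among 5 tested genes of disease-associated microglia 4 were higher and 1 lower both ways (median 1.68, adjusted p = 0.0245; adjusted p = 0.262 with an estimated correlation), with the tetraspanin CD63 at 1.68 ± 0.21. The other members of that list were too low to be tested. Over all 18 libraries APOE had 51 counts, TREM2 27, TYROBP 0, SPP1 34, GPNMB 8, LPL 1, CST7 13 and ITGAX 24. The tested genes thus do not show the program as a whole. The small RNA host gene SNHG5 rose by 3.51 ± 0.43 and the translocon subunit SEC61B by 2.62 ± 0.35. Without libraries 2 and 3 these genes kept their calls at 1.73 for SNHG5, 1.23 for SEC61B, 1.07 for NDUFB8, 0.96 for CD63, 1.29 for RPL10 and 0.69 for RPL3, as did DDIT3 at 0.99 and MT2A at 2.11.

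As in the other PFOS contrasts (rho of -0.11 and -0.17 at 24 h of 25 and 50 µM, and -0.26 at 25 µM after recovery), in these 3 libraries log2 CPM relative to vehicle fell with gene span (Spearman rho across genes of -0.28, -0.22 and -0.35), and the log2 changes of the contrast did so too (rho of -0.31 over 9781 genes, which are not independent replicates). Single vehicle libraries after recovery had rho of -0.07, -0.15 and 0.19. In all, 1743 genes were higher and 1057 lower, 1422 of them at least 2-fold, and the groups did not overlap for 31.3% of genes, where chance gives 10%. These calls use the spread shared by all groups, which can be too small for this group, whose replicates correlated least. The count of 2800 was 1600 without 50 µM recovery library 2, 255 without libraries 2 and 3 (191 higher and 64 lower, 237 of them among the 2800), and 864 with these 6 libraries alone, of which 92% were higher, against 62.2% of the 2800. Leaving out libraries 2 and 3 keeps 1 library of the group, which is assumed to vary like the other groups, so a lost call can come from lost power as well as a smaller change. Without them the median was 0.93 for ribosomal proteins (26 of 32 higher), 0.37 for the respiratory chain (2 of 28), -0.78 for the matrix (6 of 16 lower), 0.31 for disease-associated microglia genes (1 of 5) and 0.27 for NRF2 targets (3 of 17).

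**Figure D3:**
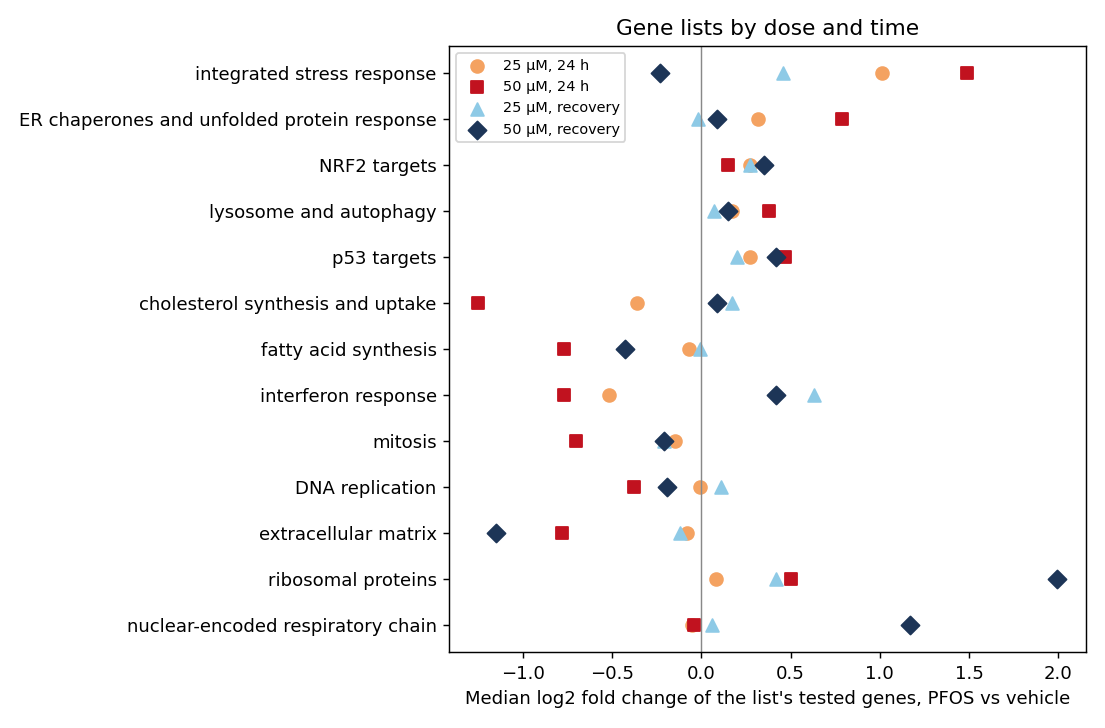
Median log2 fold change of 13 gene lists in the 4 contrasts of PFOS with vehicle, with 1 mark per list and contrast. Integrated stress response genes had medians of 1.01 and 1.49 at 24 h and -0.23 after recovery from 50 µM, cholesterol genes -1.25 at 24 h of 50 µM and 0.09 after recovery, and ribosomal proteins 1.99 after recovery from 50 µM.

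The doses also differed after recovery. NQO1 and RPL10 were higher at 50 than at 25 µM (adjusted p = 0.000335 for both), as was MT2A (adjusted p = 0.00014), and SPARC was lower (adjusted p = 0.000448). CYP51A1 and HSPA5 were not shown to differ (adjusted p = 0.363 and 0.598). The stress genes SLC6A9, STC2, ASNS, CHAC1, TRIB3 and ADM2 were lower at 50 than at 25 µM (adjusted p = 0.001, 0.00443, 0.00875, 0.0233, 0.0273 and 0.0487). DDIT3 was higher (adjusted p = 0.00155), and SLC7A11 was not shown to differ (adjusted p = 0.491). In all, 1445 genes were higher and 727 lower at 50 µM, and the groups did not overlap for 28.8% of genes, where chance gives 10%. The count of 2172 was 957 without 25 µM library 2, 3766 and 931 without 50 µM libraries 1 and 2, and 23 without 50 µM libraries 2 and 3. With these 6 libraries alone edgeR called 0, with 2000 genes at an unadjusted p under 0.05, while DESeq2 on all libraries called 2164.

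Whether the 50 µM effect itself differed between recovery and 24 h was tested as an interaction. Integrated stress response genes had a smaller effect after recovery, with 19 of 24 lower (21 over the list alone; median difference -1.44, adjusted p = 9.8e-34), led by TRIB3 at -3.87 ± 0.37. So did ER chaperones, with 9 of 19 lower and 1 higher (11 and 1 over the list alone; median -0.76, adjusted p = 4.52e-08), HSPA5 among them at -1.76 ± 0.15. For cholesterol genes the difference was positive, with 18 of 24 higher both ways (median 1.46, adjusted p = 9.09e-20) and CYP51A1 at 1.63 ± 0.20. Part of this lies in vehicle, where CYP51A1 fell by 0.83 ± 0.13 between the times, while its level at 50 µM went from 114 ± 5.23 to 198 ± 16.3 CPM. For interferon response genes the difference was also positive, with 9 of 15 higher and 0 lower (9 and 1 over the list alone, median 1.87, adjusted p = 8.68e-05). In vehicle these genes had a median change of 0.22 between the times, so a fall of vehicle does not account for their difference. The matrix genes SPARC and COL5A2, the oxidoreductase NQO1 and MT2A were not shown to differ (adjusted p = 0.791, 0.317, 0.0544 and 0.269). Ribosomal protein genes had 28 of 32 higher (29 over the list alone; median 1.43, adjusted p = 3.81e-13; adjusted p = 0.371 with an estimated correlation). Without 50 µM recovery libraries 2 and 3 edgeR called 0 ribosomal protein genes for this difference (median 0.51), and 5 of 15 interferon genes were higher (median 1.13).

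In all, the 50 µM effect differed for 1878 genes, 1147 with a positive and 731 with a negative difference. This count was 1188 and 1211 without 24 h vehicle libraries 2 and 3, 3314 without 50 µM recovery library 1, 422 without recovery libraries 2 and 3, 1082 in thinned counts and 1022 with the 12 libraries of the contrast alone. Of the 1848 genes called at 24 h, 493 were called again in the same direction after recovery (234 higher, 259 lower, where independent lists would share 160 and 101), and 86 in the opposite one. Of these 493, 420 showed no called difference between the effects. A further 550 were no longer called and had a smaller effect, and for 719 neither the recovery effect nor the difference was called. The 493 became 741 without 50 µM recovery library 1, 138 without libraries 2 and 3, 302 in thinned counts and 242 from fits of each contrast's own libraries. Of the 2800 genes called after recovery, 2221 (79.3%) had not been called at 24 h, and 994 of these had an effect larger than at 24 h by the same test.

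For 25 µM, 2 genes had an effect that differed between recovery and 24 h, and both were named after their values were seen. ASNS differed by -1.88 ± 0.28 (adjusted p = 0.00534) and SERPINE2, a serine protease inhibitor, by -1.43 ± 0.18 (adjusted p = 0.00147). Much of the ASNS difference lies in vehicle, where ASNS rose by 1.28 ± 0.20 between the times. An unadjusted p under 0.05 was found for 458 genes, and DESeq2 called 37, a fit without a filter on low counts 10, a fit of the 12 libraries alone 35 and a fit with the gene-span trend removed 5.

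Vehicle cells also changed between the sampling times, with a later harvest and fresh medium. CHAC1 was higher after recovery by 1.86 ± 0.32 (adjusted p = 0.00479), CDKN1A by 1.05 ± 0.18, and ASNS by 1.28 ± 0.20, while the smooth muscle actin ACTA2 was at 1.98 ± 0.44, a gene whose close actin relatives make its reads uncertain. TOMM40, an import channel of mitochondria (chromosome 19: 44891254-44903689), was lower by 1.91 ± 0.23 (adjusted p = 0.00063), PREP, a prolyl peptidase, by 2.07 ± 0.33, CYP51A1 by 0.83 ± 0.13 and LDHA by 0.75 ± 0.14. In all, 33 genes were higher and 63 lower, and the groups did not overlap for 18.3% of genes, where chance gives 10%. The count of 96 was 12 and 39 without 24 h vehicle libraries 2 and 3, 17 and 45 without recovery vehicle libraries 2 and 3, 31 in thinned counts, 152 by DESeq2 and 224 without a filter. CHAC1, CDKN1A, CYP51A1 and PREP lost their calls without 24 h vehicle library 2, and CHAC1 and PREP also without recovery vehicle library 2, with adjusted p over the alternatives of 3.06e-12 to 0.0971 for CHAC1, 1.31e-06 to 0.0803 for CDKN1A, 3.95e-07 to 0.0522 for CYP51A1 and 3.44e-05 to 0.0641 for PREP. ACTA2 lost its call without each of the 6 libraries (adjusted p from 0.0101 to 0.15), and LDHA without 24 h vehicle libraries 2 and 3 and recovery vehicle libraries 1 and 2 (0.000198 to 0.0973).

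Few markers of microglia were expressed at a testable level in any group. Of 19 microglia and macrophage markers 2 were tested. CD68, a lysosomal protein of phagocytes, rose by 1.66 ± 0.23 at 24 h of 50 µM PFOS and was higher by 1.44 ± 0.24 after recovery, with no call once the gene-span trend was removed (adjusted p from 1.69e-06 to 0.0765 over the alternatives). TLR4, the receptor for bacterial lipopolysaccharide, rose by 0.93 ± 0.29 at 24 h, with no call without vehicle libraries 1 and 3, without 50 µM libraries 1 and 2, or in thinned counts (adjusted p from 0.019 to 0.142). Over all 18 libraries P2RY12 had 8 counts, TMEM119 1, CSF1R 28, ITGAM 1 and PTPRC 2, and CX3CR1 and AIF1 had 0. Of 7 fibroblast and pericyte markers 1 rose and 3 fell at 24 h of 50 µM both ways (median -0.58, adjusted p = 0.32), with the surface enzyme NT5E at 2.14 ± 0.19 and the surface glycoprotein THY1 at -1.5 ± 0.17. Of 2 tested astrocyte markers 0 were called by edgeR in this contrast (median 0.17), of 2 neuron markers SNAP25, a vesicle fusion protein, rose by 1.74 ± 0.42 (median 0.59; no call without 50 µM library 3, adjusted p from 0.00134 to 0.0554), and of 2 epithelial markers the keratin KRT18 rose by 0.35 ± 0.12 (median 0.16). KRT18 lost this call without each of the 6 libraries (adjusted p from 0.00581 to 0.441).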

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

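In this part, the test against a gene neighbouring RPLP0P2 and the tests by splits of the libraries were planned before their results were seen, and all other tests of explanations were chosen after the result was seen. The results listed here stand out because the effect of PFOS differed between recovery and 24 h by a test of the difference itself, which held for 54 of the 99 named genes and 9 lists at 50 µM.

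The 50 µM effect was lower after recovery (log2 difference, recovery minus 24 h) for TRIB3 -3.87, SLC6A9 -3.79, CHAC1 -3.41, ADM2 -3.39, STC2 -2.66, SLC7A11 -2.39, HSPA5 -1.76, HERPUD1 -1.51, TXNRD1 -1.39 and HSP90AB1 -1. It was also lower for PTX3 -3.32, LOX -2.61, ABCA1 -2.51, LURAP1L -2.03, TLR4 -1.55, WIPI1 -1.48, MAP1LC3B -1.08 and PLIN2 -1.03. The remaining negative values were RPLP0P2 -4.32, HIST1H4H -1.25, KAT7 -1.14, CDKN1A -0.93 and FOSL1 -0.67. Part of some of these differences lies in vehicle. Between the times vehicle rose, with a call, for CHAC1 by 1.86, ADM2 by 1.52, ABCA1 by 1.16 and CDKN1A by 1.05. For CDKN1A the rise in vehicle was larger than the difference itself, so its level at 50 µM did not fall.

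The difference was positive for EBP 2.01, ACSS2 2.28, CYP51A1 1.63, NPC2 1.42, LDHA 1.25, ADM 1.16 and ECH1 0.97. It was positive for the antiviral genes IFIT1 3.24, ISG15 2.93 and MX1 2.51, and for the proliferation genes PCNA 1.54, AURKA 0.85, RRM2 0.81 and MCM6 0.81. It was also positive for HSPE1 3.17, SEC61B 2.26, SNHG5 2.03, NDUFB8 1.52, SOD2 1.24, RPL10 1.22 and CD63 1.11. Further values were DCDC2 6.82 (a fitted value, since the 50 µM libraries at 24 h had 0 counts), ZBED2 4.20, FHDC1 3.86, NPPB 3.40, ACTC1 2.85, HOPX 2.49, THY1 1.08, TGFB2 0.88, TAGLN 0.81 and KRT18 0.72. Here too vehicle had a part, since between the times it changed by -0.84 for ACSS2, -0.83 for CYP51A1 and -0.75 for LDHA, all called.

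Some of these differences were no longer called without 50 µM recovery libraries 2 and 3, which leaves 1 library in the group. Their values were then SNHG5 0.27, RPL10 0.40, CD63 0.40, ECH1 0.55, NPC2 0.56, PCNA 0.64, NDUFB8 0.69, SOD2 0.72, SEC61B 0.88, HSPE1 1.63, HOPX 1.98, NPPB 2.33 and ACTC1 2.57. The others were TAGLN 0.41, KRT18 0.56, RRM2 0.60, MCM6 0.65, FOSL1 -0.70, KAT7 -0.76, HSP90AB1 -0.93, HIST1H4H -1.11 and TLR4 -1.23.

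At 25 µM the effect differed for ASNS (-1.88) and SERPINE2 (-1.43). Among lists at 50 µM the median difference was -1.44 for the integrated stress response, -0.76 for ER chaperones, -0.32 for lysosome and autophagy genes and -0.35 for the matrix (adjusted p = 0.527 with an estimated correlation). It was 1.46 for cholesterol genes, 1.87 for the interferon response, 0.37 for mitosis (adjusted p = 0.0867 with an estimated correlation), and 1.21 for the respiratory chain and 1.43 for ribosomal proteins (adjusted p = 0.371 with an estimated correlation for both). Without 50 µM recovery libraries 2 and 3 it was 0.32 for the respiratory chain and 0.51 for ribosomal proteins, with 0 members called by edgeR in both from the 1 library left, 1.13 for the interferon response (5 members called instead of 9) and -0.02 for the matrix (1 member lower).

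Ribosomal protein genes after recovery from 50 µM (median 1.99) could reflect the drug's aftermath or a property of these 3 libraries. A trend of the libraries with gene span does not account for the whole of it: with the trend removed the median was 1.57 (quartiles 1.18 to 1.80), with 29 of 32 members called. Lower depth does not account for it either, since 32 of 32 members were called in counts thinned to the smallest library. The difference of library 2 from library 1 in this group and that of library 2 from the other vehicle recovery libraries correlated at 0.28 across 9847 genes, which leaves open a difference between libraries that also separates replicates. Without libraries 2 and 3 the median was 0.93, so its size rests on them.

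Integrated stress response and cholesterol genes lay closer to vehicle after recovery from 50 µM, which could follow removal of PFOS, a change of the vehicle cells, or the libraries that stand apart. Compared directly with 50 µM at 24 h, the recovery group had a median change of -1.31 (quartiles -1.80 to -0.97) for the 24 stress genes and 1.07 (0.75 to 1.87) for the 24 cholesterol genes. Vehicle cells changed by medians of 0.39 and -0.28 over the same time, so a shift of vehicle alone does not account for it. Without libraries 2 and 3 the median difference between effects was -1.55 (-2.39 to -1.40) and 1.22 (0.91 to 1.60). Fresh medium and later harvest were the same in all recovery groups, while loss of stressed cells during recovery was not tested.

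RPLP0P2, a transcribed pseudogene (chromosome 11: 61615036-61639449, uncertain because of its parent gene), had a log2 change of 6.01 at 24 h of 50 µM PFOS. Reads shared with the parent gene RPLP0 would be expected to follow RPLP0, which changed by 0.75 (adjusted p = 0.0111). Of its neighbours, the tested gene within 100 kb, DAGLA, changed by 0.27 (adjusted p = 0.597), but SYT7, too low to be tested, had 0, 1 and 9 counts over the 3 libraries at 24 h of vehicle, 25 and 50 µM, and 1, 1 and 0 after recovery. RPLP0P2 had 13, 43 and 462 counts, and 14, 16 and 17, which is the same order at 24 h, so transcription from a neighbour is not excluded. What the reads come from stays open.

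Splits of the same libraries into other groups of 3 are too few to test a single contrast, since the lowest possible share is 1 of 10 (0.1). At 24 h the real count was 122 at 25 µM, 1848 at 50 µM and 729 between the doses, and the highest other count was 0 in each. After recovery it was 0 at 25 µM, as in all 10 splits. For 50 µM after recovery a wrong split gave 1037 genes against 2800, and for 50 against 25 µM 1341 against 2172, which points to a structure of the samples. Every such split keeps 2 of the 3 dosed libraries together, so an uneven effect of the dose in libraries 2 and 3 and a difference unrelated to dose are not told apart. For vehicle over time the counts were 96 and 1. Lists called were 10 against 6 at 25 µM, 15 against 11 at 50 µM, 9 against 6 after recovery from 25 µM and 6 against 5 after recovery from 50 µM. For the difference between effects, 2 of 60 splits reached 1878 genes at 50 µM, the real one included. The other of the 2 gave 2057, so a wrong split can give a count as large as the real one. At 25 µM 4 of 60 splits reached 2 genes, with a highest count of 204, so chance is not excluded there, and neither is it for the 9 lists called at 50 µM, which 12 of 60 splits reached, none with more than 9.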

How the results depend on the processing

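In this part, the refits without libraries 2 and 3 of the 50 µM recovery group and with the gene-span trend removed were chosen after the result was seen, and all other alternatives were planned. Of 278 calls of named genes 273 were kept by DESeq2, 274 with RLE scaling, 268 without a filter and 257 with the span trend removed. With the contrast's own libraries 239 of 266 were kept, in thinned counts 200 of 245, and without libraries 2 and 3 54 of 110. Genes that turned direction after recovery from 50 µM were CXCL1 at -0.05 without libraries 2 and 3, and ADM at -0.76, HIST1H4H at -1.38, HSPA5 at -0.34 and IER3 at -0.04 with the span trend removed. With a correlation estimated from the data, the lists called were 7 at 24 h of 50 µM, 5 after recovery from 25 µM, 1 after recovery from 50 µM and 5 for the difference between 50 µM effects, and fry called 18 after recovery from 50 µM. Without a filter the counts of genes were 5 (25 µM after recovery), 10 (difference between 25 µM effects) and 224 (vehicle over time), and by DESeq2 1, 37 and 152. With only the contrast's libraries they were 416 and 2860 at 24 h of 25 and 50 µM, 864 for 50 µM after recovery (92% higher), 1932 between doses at 24 h, 0 between doses after recovery (edgeR, 2000 at an unadjusted p under 0.05), and 35 and 1022 for the differences between effects at 25 and 50 µM. The shared genes were then 242 for 50 µM at both times and 372 for both doses. Fewer libraries change the estimate of the spread. The counts named here rose, except where the 50 µM recovery group took part, where they fell. Replicates of that group correlated least, while the main fit gives all groups 1 shared spread. Such a spread can be too small for that group and too large for the others. The SE and adjusted p of contrasts with that group may thus be too small, and beyond that the cause was not tested. In counts thinned to 581011 per library, which shows what depth limits, they were 62 and 1184 at 24 h, 386 between doses, 1082 for the difference between 50 µM effects, 31 for vehicle over time, and 302 and 59 shared. Without libraries 2 and 3, which leaves 1 library in the group, assumed to vary like the other groups, they were 255 for 50 µM after recovery (74.9% higher, against 62.2%), 23 between doses after recovery (43.5% higher, against 66.5%), 422 for the difference between 50 µM effects (50.2% higher, against 61.1%) and 138 shared. With the span trend removed 5 genes differed between 25 µM effects, and the cause was not tested. Between doses after recovery 53.6% were higher without a filter. Leaving out each library in turn, with fewer libraries, gave 49 to 75 genes at 24 h of 25 µM, 1139 to 1707 at 50 µM, 0 to 0 for 25 µM after recovery (edgeR, 379 to 768 at an unadjusted p under 0.05; DESeq2 called 1 on all libraries), 1600 to 4074 for 50 µM after recovery, 347 to 541 and 931 to 3766 between doses at 24 h and after recovery, 2 to 3 and 1188 to 3314 for the differences between effects, 12 to 72 for vehicle over time, and 349 to 741 and 48 to 97 shared. Same-numbered libraries correlated at -0.34 to 0.39 in their deviations from group means and 5 of 18 matched their own number best. Pairing by number was thus not seen, although this check cannot exclude it. The replicate block gave 54 genes for vehicle over time and left all other counts within 1.5-fold, and the cause was not tested. Removal of mitochondrially encoded genes was not run, since the table holds 0 of them.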

Other observations

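In this part no explanation was tested, and the genes follow the rule fixed in advance. Several genes with large changes at 24 h of 50 µM PFOS belong to none of the programs described. SERPINB2, an inhibitor of plasminogen activators, rose by 5.95 ± 0.82 and THBD, the thrombin receptor thrombomodulin, by 4.77 ± 0.59 (0.437 to 16.4 ± 6.12 CPM, n = 3). SERPINB2 lay near the floor in vehicle, so the size of its fold is uncertain. ZBED2, a transcription factor with a zinc finger, changed by -3.69 ± 0.45, the cardiac actin ACTC1 by -4.01 ± 0.59 (a gene with close relatives, so its reads are uncertain) and the natriuretic peptide gene NPPB by -3.41 ± 0.60. DCDC2, a microtubule-binding protein, had 6.58 ± 0.443 CPM in vehicle and 0 counts at 50 µM, at least 8.44-fold lower.

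After recovery from 50 µM, G0S2, an inhibitor of lipolysis, was higher by 5.31 ± 0.82, the mitochondrial chaperonin HSPE1 by 2.77 ± 0.43 and the DNA clamp PCNA by 1.27 ± 0.24. OTUB2, a deubiquitinase, changed by -2.84 ± 0.46 and the smooth muscle actin ACTG2 by -2.67 ± 0.41. G0S2, HSPE1 and PCNA lost their calls without libraries 2 and 3 of that group, where 1 library is left and their log2 changes were 1.87, 1.22 and 0.36, with adjusted p over the alternatives from 6.35e-11 to 0.688, 6.81e-21 to 0.187 and 1.26e-08 to 0.449.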
